A study of Mus musculus with 8 samples.

How the data were processed

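The deposited Agilent text files were read, 8 arrays scanned in Cy3 and extracted with Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12, per the file headers. Their processed signals were background-subtracted intensities on a linear scale, per the file headers, and background, outlier and saturation columns were 0 or 1 flags, per the file headers. The deposited series matrix held log2 values scaled to the 75th percentile, per the labels, and centred on each probe's median over the 8 arrays. The chosen measure was log2 of the processed signal minus log2 of the array's 75th percentile over noncontrol probes.

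Control spots were removed. Spots flagged as outliers by the deposited files, 191 to 317 per array, were left out, and remaining spots of a probe were averaged. A probe was kept when it was well above background on every array of at least 1 of the 4 groups. The 75th percentile of signal ran from 315 (Fra-2 knockout 1) to 470 (Fra-1 control 2), the coefficient of variation of repeated spots from 4.25% to 5.87%, and 1 spot was saturated. The lowest normalized log2 signal well above background was −3.85 on Fra-2 knockout 1 and −4.45 to −4.98 on the others. For genes below background in a group, log2 differences are fitted values that include background, and a fold is given only as a bound, where the other group was above background on both arrays; dim genes were read less surely on Fra-2 knockout 1. The number of arrays limits precision.

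Probes were named by accession through a RefSeq table of assembly GRCm38.p6, used only for names and neighbours, whereas array headers gave mm9. Of 55681 noncontrol probes, 28026 were named, for 21154 genes. The brightest probe on average stood for each gene. Limma 3.58.1 in R 4.3.3 fitted group means to all 8 arrays (residual degrees of freedom 4, prior 1.99), and p was adjusted by the Benjamini-Hochberg method within each comparison. A feature was called at an adjusted p under 0.05. Values with ± are means and standard deviations of 2 arrays, and SE is the moderated standard error. Comparisons were Fra-1 knockout against its controls, Fra-2 knockout against its controls, the difference of these, and Fra-1 controls against Fra-2 controls. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

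Gene lists were written from general knowledge before the data were examined: 38 lists with 872 entries, of which 856 were on the array. Of these, 37 were tested with camera at a correlation of 0.01, with camera at an estimated correlation and with fry, directional and mixed; the sex-linked list had a single gene above background and was not tested. Within each list, p was also adjusted over the list alone. Lists can share members and are not independent: of the fibroblast and mesothelial genes, Col1a1, Col1a2 and Col3a1 are also matrix genes, C3 a complement gene, and Wt1 and Slpi large resident macrophage markers.

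Genes were named by a rule set before the data were examined. Fosl1, Fosl2, Lyz2, Arg1, Nos2 and the strain markers Nnt and Casp4 were always named; Nnt was not among tested genes. Per comparison, the rule took the 12 called genes with the largest changes in each direction among those whose arrays did not overlap, and the 10 with the smallest p where fewer than 10 were called. Per list it took up to 4 called members, or up to 2 with the smallest p. Clone-like and predicted names were counted but not named.

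Alternatives set before the data were examined were quantile normalization, normexp background correction with an offset of 50, the series matrix, no filter, a filter on all 8 arrays, the mean of probes, a slide term, only the groups compared, both control groups pooled, a trended prior, a log2 fold change of at least 1, other list tests, and leaving out each array. The files hold median but no mean raw signals, so normexp was run on medians, which was chosen after the data were seen, as was a common floor at the highest detection level. Slide 1 held Fra-2 control 1, Fra-2 knockout 1, both Fra-1 controls and Fra-1 knockout 1, and slide 2 the other arrays.

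The pipeline was tested on simulated data with 200 changed genes in 5 runs. Changes of 1, 2 and 4 log2 units were found in 27.2%, 76.7% and 95.8% of cases in the Fra-1 comparison, 26.6%, 85.4% and 96.4% in Fra-2, and 26.9%, 78.5% and 97.0% between controls. False calls were 5.6%, 5.6% and 5.1%. So many changed genes loosen the Benjamini-Hochberg threshold. In the data only 3 and 2 features were called in the Fra-1 and Fra-2 comparisons, so the threshold there was stricter. The shares found in these runs therefore overstate what the knockout comparisons could find. A shifted list was called in 5 of 5 runs, and other lists 0, 0 and 3 times over all runs. The simulated noise was independent between genes, whereas the shifted list, cholesterol synthesis, had an estimated correlation of 0.36 in the data. These runs therefore could not test camera at a preset correlation on correlated genes.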

Results

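Peritoneal macrophages from Fra-1 knockout mice and their floxed littermates, and from Fra-2 knockout mice and theirs, were compared on 8 single-colour Agilent arrays, 2 per group. Fra-1 (gene Fosl1) and Fra-2 (gene Fosl2) are transcription factors of the AP-1 family, which pair with Jun proteins on DNA. Per the labels, Fosl1 was deleted with Mx Cre, which interferon switches on, and Fosl2 with LysM Cre, which is active in myeloid cells. Cells came from peritoneal lavage of 8-week-old mice of either sex on a mixed 129 and C57Bl6 background, were plated overnight, and only adherent cells were used. Only the Fra-1 line was labelled thioglycollate elicited. Of 59305 noncontrol spots per array, 47.7% (Fra-2 knockout 1) to 57.6% (Fra-2 control 1) were well above background. A total of 31159 probes passed the filter, and 22910 features were tested, of which 14395 (62.8%) carried a gene name.

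The largest difference in gene expression lay between the arrays of the mouse lines. Line, thioglycollate label and preparation went together, so it cannot be assigned to the line alone. Principal component 1 held 77.3% of the variance and separated the Fra-1 line from the Fra-2 line. Component 3, with 5.56%, placed the Fra-1 knockout arrays at 39.5 and 35.3 and the Fra-1 controls at −45.1 and −28.0, while Fra-2 line arrays lay between −7.37 and 10.1. Component 2, with 6.33%, ran from Fra-2 knockout 1 at −66.3 to Fra-2 control 2 at 43.7. Correlations were 0.910 to 0.922 between lines, 0.977 to 0.988 between groups of the same line, and 0.983 to 0.992 within groups. Xist, the RNA that silences an X chromosome and marks female cells, had values from 0.19 to 1.65 on all 8 arrays.

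**Figure D1:**
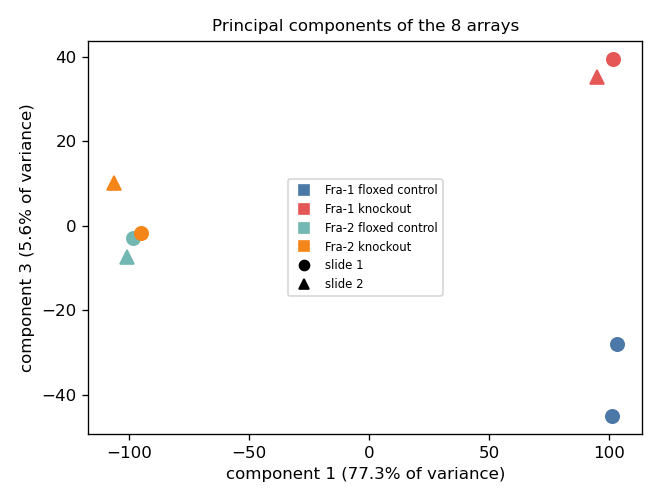
Principal component 1 (x axis, 77.3% of variance) against component 3 (y axis) of normalized log2 signal on the 8 arrays; each point is an array, coloured by group, with circles for slide 1 and triangles for slide 2. The mouse lines separate along x, and the Fra-1 knockout and control arrays separate along y.

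Genes of the peritoneal stroma were lower in Fra-1 knockouts by camera at a preset correlation, but with an estimated correlation 0 of 37 lists were called (smallest adjusted p = 0.890) and by directional fry 0 (smallest adjusted p = 0.541). Genes of fibroblasts, the collagen-making cells of connective tissue, had a median log2 fold change of −1.29, and genes of mesothelium, the lining of the peritoneal cavity, −0.84. Gene lists of the hypoxia response, interferon response, cholesterol synthesis, glycolysis, unfolded protein response and MHC class II presentation had positive medians of 0.19 to 0.48. Markers of macrophages in general (median −0.01), markers of large resident peritoneal macrophages (0.02) and targets of NF-kappaB (0.04) were not called by camera. Mixed fry, which takes changes in both directions, called 2 lists, uptake of apoptotic cells and large resident macrophage markers (adjusted p = 6.29e-04), the latter with 4 members higher and 4 lower by unadjusted p under 0.05. Among single features, with 1 probe per gene, 3 passed, all lower in the knockout.

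Fosl1, the targeted gene, had a normalized log2 signal of −2.35 ± 0.54 in Fra-1 controls and −4.48 ± 0.43, below background on both arrays, in knockouts. Its log2 fold change was −2.13 (SE 0.53, limma adjusted p = 0.364), at least 3.91-fold lower, and it was not called. Bounds of this kind were computed against the lowest level well above background on the array, or the gene's own value where that was higher. They depend on that level, and a common floor can give a smaller change than the bound. The log2 fold change of Fosl1 was −2.44 within slide 1, −2.07 with a slide term and −1.51 with a common floor. Fosl2 was 2.99 ± 0.19 in controls and 3.17 ± 0.03 in knockouts (0.17, adjusted p = 0.869). Lyz2, which encodes lysozyme and carries the Cre in the LysM line, was 8.47 ± 0.35 and 8.43 ± 0.12. Nos2, which makes nitric oxide, differed by 0.67 (adjusted p = 0.677). Casp4, an inflammatory caspase that carries a deletion in some 129 strains, was 2.94 ± 0.02 and 3.39 ± 0.02 (0.45, adjusted p = 0.850).

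Capn6, a calpain without protease activity that binds microtubules, fell from −4.13 ± 0.05 to −6.57 ± 0.03 in Fra-1 knockouts (−2.44, SE 0.12, adjusted p = 0.0221, at least 1.26-fold). Its adjusted p ran from 0.0149 to 1.0 over the alternatives, with −2.46 within slide 1 and −2.42 (adjusted p = 0.125) with a slide term. Pcsk6, a convertase that cleaves precursors of secreted proteins, fell from −4.48 ± 0.02 to −6.67 ± 0.02 (−2.19, SE 0.14, adjusted p = 0.0309, range 0.0297 to 1.0). Pcsk6 lay so close to background in controls that no fold could be bounded, and its value was −2.17 both within slide 1 and with a slide term (adjusted p = 0.131). An unnamed transcript, ENSMUST00000045546, fell from −3.91 to −6.76 (−2.84, SE 0.16, adjusted p = 0.0221, range 0.0103 to 1.0, at least 1.47-fold; −2.85 within slide 1, −2.79 with a slide term). All were below background in the knockout, and with a common floor Capn6, Pcsk6 and the unnamed transcript each changed by 0.00. Leaving out any Fra-1 array or either Fra-2 control ended the calls of Capn6 (−2.40 to −2.48, adjusted p 0.0780 to 0.154), Pcsk6 (−2.17 to −2.20, 0.0780 to 0.213) and the unnamed transcript (−2.81 to −2.88, 0.0780 to 0.178). By unadjusted p under 0.05, 2025 features differed, against 1146 expected by chance, 780 higher and 1245 lower. A dimmer probe of Syn3, a synapsin, which did not stand for its gene and was chosen after its values were seen, was −6.48 and −7.07 on control arrays and −1.49 and −1.81 on knockout arrays (5.13, adjusted p = 0.0294 in a fit of all probes). The arrays did not overlap between groups for 46.4% of features, where chance gives 33.3%.

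The genes with the smallest p beyond these missed the threshold. Nfia, a nuclear factor I transcription factor, was −3.36 ± 0.05 in controls and −4.87 ± 0.03 in Fra-1 knockouts (−1.51, adjusted p = 0.0755, at least 2.16-fold). Irs1, the adaptor of the insulin receptor, differed by −1.91 (adjusted p = 0.0755, at least 2.68-fold), and Tmem100, a membrane protein of bone morphogenetic protein signalling, by −3.05 (adjusted p = 0.0755, at least 2.24-fold). Dlk1, a Notch-related protein of progenitor cells, was −1.76 ± 0.19 and −4.51 ± 0.45 (−2.75, adjusted p = 0.0847, at least 5.96-fold). Mycn, a relative of Myc, had −3.41 (adjusted p = 0.0869, at least 2.57-fold), and Glb1l2, a galactosidase-like gene, −1.84 (adjusted p = 0.0847). Lvrn, an aminopeptidase (3.32, at least 2.49-fold), and H2-M9, an MHC class I-like gene (3.06), both had adjusted p = 0.0884. Arg1, which splits arginine and marks alternatively activated macrophages, was 1.72 and 5.17 on the control arrays and 6.03 and 5.48 on the knockout arrays (2.31, SE 1.06, adjusted p = 0.612; 0.59 without Fra-1 control 1).

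Of 37 gene lists, camera with a correlation of 0.01 called 10 in the Fra-1 comparison, 4 lower and 6 higher. Without the filter on dim probes the calls of cholesterol synthesis (0.22, adjusted p = 0.0661), glycolysis (0.25, 0.0757), MHC class II (0.29, 0.0831) and the unfolded protein response (0.19, 0.0962) were lost, with the mean of probes those of cell cycle (−0.15, 0.0611) and matrix genes (−0.30, 0.0578), and with a common floor that of MHC class II (0.25, 0.0577). The lower lists held stromal, matrix and cell cycle genes. Fibroblast markers (17 genes, median −1.29, 16 negative, camera adjusted p = 7.36e-09; adjusted p = 0.890 with an estimated correlation) were −1.47 with a slide term and −1.02 within slide 1. Adjusted over the list alone, 6 members were lower, among them Sparc, a collagen-binding glycoprotein (7.52 ± 0.31 to 6.23 ± 0.40 on its brightest probe, −0.74 and 0.13 on the others), and Dcn, the proteoglycan decorin (4.84 ± 0.44 to 3.68 ± 0.54). The fibroblast call held without any single array. Mesothelial markers (15 genes, median −0.84, 13 negative, adjusted p = 2.91e-04; adjusted p = 0.890 with an estimated correlation) were −0.45 with a slide term and −0.71 within slide 1. There 3 members were lower adjusted over the list alone, including Lrrn4, a leucine-rich repeat membrane protein (−2.10), and Bnc1, a zinc finger protein of epithelia (−2.03). Without Fra-1 control 2 the mesothelial median was −0.50 and the call was lost (adjusted p = 0.0589). 

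Matrix and protease genes (25 genes, median −0.31, 18 negative, camera adjusted p = 0.0311; adjusted p = 0.890 with an estimated correlation) were −0.47 with a slide term and −0.36 within slide 1; its collagen genes Col1a1, Col1a2 and Col3a1 are also in the fibroblast list. Adjusted over the list alone, 1 was lower: Vcan, the proteoglycan versican (−1.56 ± 0.28 to −3.10 ± 0.21, and −0.20 on its other probe); Timp3, an inhibitor of metalloproteinases, had −1.18. That call was lost without Fra-1 control 2 (−0.15, adjusted p = 0.418) or Fra-1 knockout 2 (−0.36, adjusted p = 0.122). Cell cycle genes (39 genes, median −0.13, 30 negative, adjusted p = 0.0329; adjusted p = 0.955 with an estimated correlation) included Cdc20, which triggers anaphase (−0.81), and Mcm4 of the replicative helicase (−0.35), and 0 passed limma adjusted over the list alone, 1 by unadjusted p under 0.05. Their median was −0.11 with a slide term, −0.20 within slide 1 and 0.07 without Fra-1 control 2, which reversed it. Without Fra-1 control 1 it was −0.36, and the call was lost without Fra-1 knockout 1 (−0.11, adjusted p = 0.147) or Fra-1 knockout 2 (−0.20, adjusted p = 0.0538).

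Hypoxia response genes (22 genes, median 0.48, 19 positive, camera adjusted p = 2.97e-04; adjusted p = 0.890 with an estimated correlation) included Car9, a carbonic anhydrase (1.08 ± 0.24 to 1.55 ± 0.09), and P4ha1, a collagen prolyl hydroxylase (0.52). Their median was 0.47 with a slide term, 0.59 within slide 1, 0.28 without Fra-1 control 1 (adjusted p = 0.0975), 0.73 without Fra-1 control 2 and 0.41 without Fra-1 knockout 1 (adjusted p = 0.0557). Glycolysis genes (22 genes, median 0.25, 20 positive, adjusted p = 0.0206; adjusted p = 0.955 with an estimated correlation) included Hk1, a hexokinase (0.42), and Pdk1, which holds pyruvate out of mitochondria (0.63), with 0.25 within slide 1 and 0.10 with a slide term, where the call was lost (adjusted p = 0.304). Without Fra-1 control 1 glycolysis had 0.21 (adjusted p = 0.255) and without Fra-1 knockout 1 0.32 (adjusted p = 0.147). Cholesterol synthesis (24 genes, median 0.26, 21 positive, adjusted p = 0.00223; adjusted p = 0.890 with an estimated correlation) included Sqle, squalene epoxidase (0.56), and Mvk, mevalonate kinase (0.39). Its median was 0.17 with a slide term, 0.20 within slide 1 and 0.12 without Fra-1 control 1 (adjusted p = 0.0750). No member of these lists passed limma adjusted over the list alone.

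Interferon-stimulated genes (37 genes, median 0.31, 32 positive, camera adjusted p = 3.54e-04; adjusted p = 0.890 with an estimated correlation) included Usp18, which removes the ubiquitin-like ISG15 (1.20 ± 0.03 to 1.87 ± 0.03), and Zbp1, a sensor of Z-form nucleic acid (0.80). Their median was 0.28 with a slide term, 0.52 within slide 1, 0.15 without Fra-1 knockout 1 (adjusted p = 0.437), 0.52 without Fra-1 knockout 2 and 0.26 without Fra-1 control 2 (adjusted p = 0.0589). The unfolded protein response (24 genes, median 0.19, 19 positive, adjusted p = 0.0206; adjusted p = 0.890 with an estimated correlation) included Calr, a chaperone of the endoplasmic reticulum (0.33), and Ddit3, a stress transcription factor (0.50). Its median was 0.14 with a slide term, 0.19 within slide 1, 0.14 without Fra-1 control 1 (adjusted p = 0.198) and 0.19 without Fra-1 knockout 2 (adjusted p = 0.0550). MHC class II presentation (15 genes, median 0.29, 14 positive, adjusted p = 0.0274; adjusted p = 0.890 with an estimated correlation) included H2-Eb2 (0.63) and H2-DMa (0.45), parts of the machinery that shows peptides to T cells. Its median was 0.43 with a slide term, 0.27 within slide 1, 0.14 without Fra-1 control 1 (adjusted p = 0.198) and 0.29 without Fra-1 knockout 1 (adjusted p = 0.116). No member of these lists passed limma adjusted over the list alone.

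**Figure D2:**
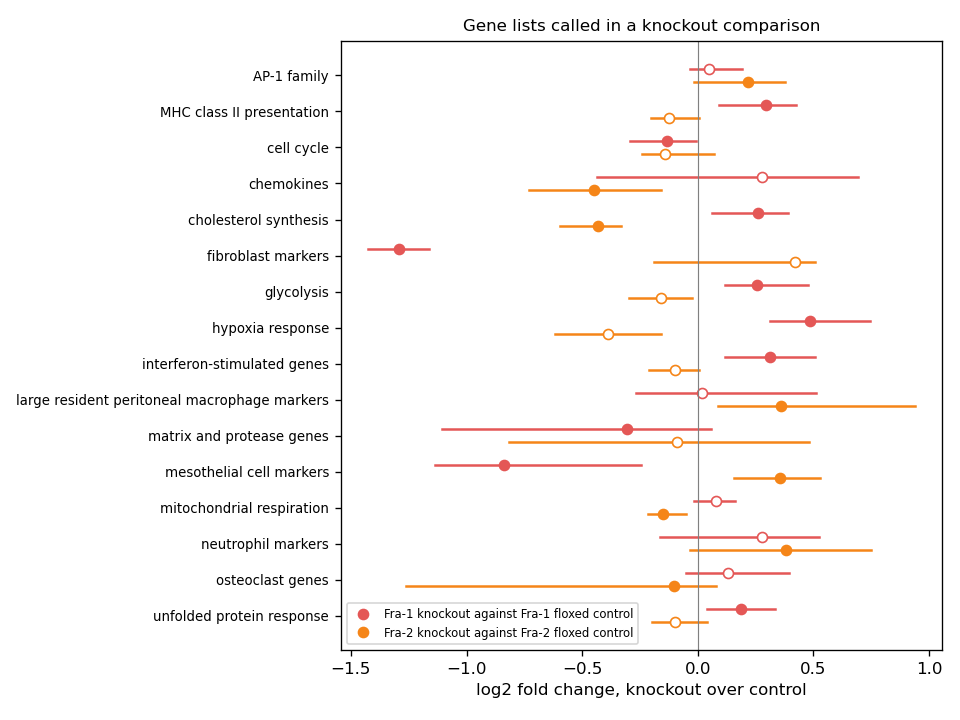
Log2 fold change of knockout over control (x axis) for the 16 gene lists called in a knockout comparison; points are list medians, horizontal lines run from the 25th to the 75th percentile of members, red is Fra-1 and orange Fra-2, and filled points were called by camera. Fibroblast and mesothelial genes lie to the left in Fra-1, and cholesterol synthesis lies on opposite sides in the knockouts.

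Cholesterol synthesis genes were lower in Fra-2 knockouts by camera at a preset correlation (24 of 24 negative, median −0.43; adjusted p = 0.773 with an estimated correlation). By the same test chemokines, mitochondrial respiration and osteoclast genes were lower, and markers of large resident peritoneal macrophages, neutrophils, mesothelium and the AP-1 family higher. With an estimated correlation 0 of 37 lists were called (smallest adjusted p = 0.710), and by directional fry 0 (smallest adjusted p = 0.0501), while mixed fry called 13. Fosl2 itself was not called, and its probes differed in direction. Among single features, 2 passed, 1 higher and 1 lower, neither matched to a gene name by the naming used here.

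Fosl2 read by its brighter probe was 5.54 ± 0.04 in Fra-2 controls and 6.78 ± 0.50 in arrays labelled Fra-2 knockout (1.24, SE 0.24, limma adjusted p = 0.207), with 0.91 within slide 1, 1.56 within slide 2 and 1.24 with a slide term. Its dimmer probe went the other way, −2.62 to −3.89 (−1.27, SE 0.30, adjusted p = 0.298), and the mean of the probes was −0.02. Where the probes lie relative to the deleted part of the gene was not known. Fosl1 was −2.76 ± 0.33 in controls and −2.12 ± 1.03 in knockouts (0.64, adjusted p = 0.852). Lyz2 was 9.17 ± 0.33 and 8.80 ± 0.00 (−0.37; −0.14 and −0.61 within the slides). Nos2 had −1.30 (adjusted p = 0.430; −1.67 and −0.92 within the slides). Arg1 was 5.96 and 6.16 on control arrays and 3.00 and 4.05 on knockout arrays (−2.54, SE 1.06, adjusted p = 0.575). Casp4 was 5.17 and 3.73 in controls and 3.49 and 4.76 in knockouts, a spread within groups that its dimmer probe shared.

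**Figure D3:**
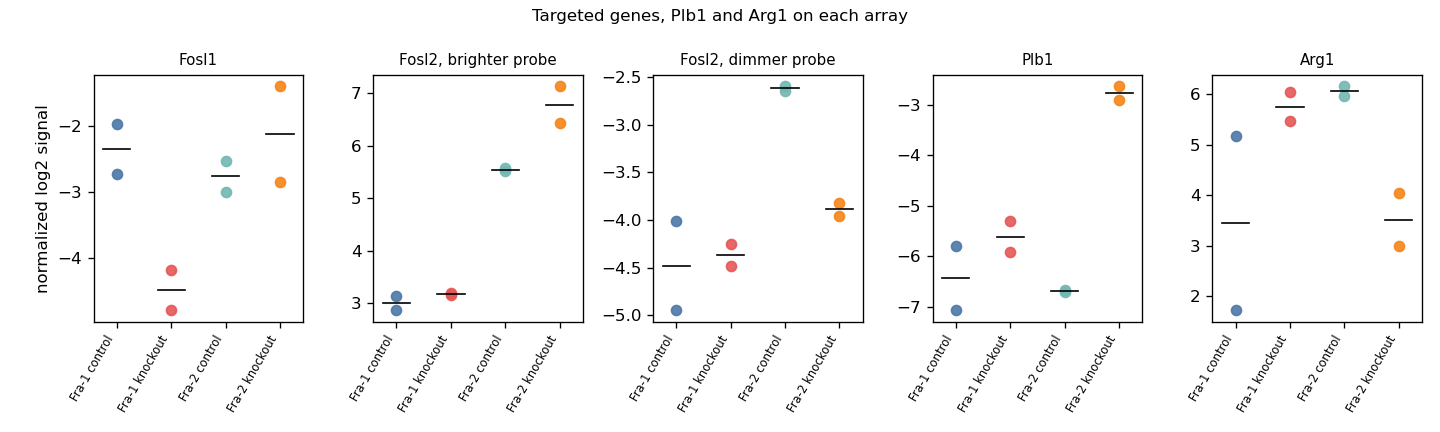
Normalized log2 signal (y axis) of Fosl1, both Fosl2 probes, Plb1 and Arg1 in the 4 groups (x axis); points are arrays and black lines are group means. The Fosl2 probes move in opposite directions between the Fra-2 groups, and Arg1 is low on a single Fra-1 control array.

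The feature that rose in Fra-2 knockouts, NM_021304, was not matched to a symbol by the naming used here. It went from −1.05 to 1.36 (2.41, SE 0.15, limma adjusted p = 0.0430, range 0.00149 to 0.615). Its value was 2.16 within slide 1, 2.65 within slide 2 and 2.41 with a slide term (adjusted p = 0.146). The feature that fell was a probe for the region 96104418–96141693 of chromosome 3 (build mm9 per the array header), from −2.50 to −5.87 (−3.37, SE 0.18, adjusted p = 0.0358, range 0.0232 to 0.622, at least 3.19-fold). Within the slides it had −3.25 and −3.49, and with a slide term −3.37 (adjusted p = 0.146). With single arrays left out, the call of NM_021304 was kept only without Fra-2 knockout 2 and lost without any other (2.32 to 2.57, adjusted p 0.0550 to 0.183). That of the chromosome 3 probe was lost without any Fra-2 array but knockout 2, and without either Fra-1 knockout (−3.32 to −3.44, adjusted p 0.0550 to 0.183). By unadjusted p under 0.05, 690 features were higher and 1330 lower, and 35.1% had arrays that did not overlap, where chance gives 33.3%.

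The genes with the smallest p in the Fra-2 comparison after these missed the threshold. Runx2, the osteoblast transcription factor, had 2.49 (adjusted p = 0.0666) on a probe that was above background on 1 knockout array alone, and 0.91 and −1.25 on its other probes, so no fold is given. Dnm1, the dynamin of synapses, was 2.46 ± 0.63 and −1.52 ± 0.23 (−3.98, adjusted p = 0.0666; −4.59 and −3.36 within the slides), but another Dnm1 probe, above background on all arrays, had 0.04. Galnt9, which starts O-linked glycans, had −4.93 (adjusted p = 0.0666, at least 8.47-fold), and Syn3, a synapsin, −3.93 (adjusted p = 0.0843, at least 3.61-fold) on its brighter probe, the other being below background in both Fra-2 groups. Il1r2, the decoy receptor of interleukin 1, was −4.49 ± 0.00 and −1.20 ± 0.01 (3.29, adjusted p = 0.0962, at least 9.77-fold; 3.29 and 3.28 within the slides). Also with adjusted p = 0.0962 were Hepacam2, an adhesion protein (2.13), Snhg3, a small nucleolar RNA host (1.75), Capn5, a calpain (−1.31), and Glb1l2 (−1.60). Cela1, an elastase, had −1.82 (adjusted p = 0.0666).

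Camera with a correlation of 0.01 called 8 of 37 lists in the Fra-2 comparison. Without the filter on dim probes the calls of the AP-1 family (0.22, adjusted p = 0.105) and mesothelial markers (0.34, adjusted p = 0.154) were lost. Cholesterol synthesis (24 genes, median −0.43, camera adjusted p = 1.38e-10; adjusted p = 0.773 with an estimated correlation) was −0.43 with a slide term, −0.61 within slide 1 and −0.35 within slide 2. In this list 13 members were lower adjusted over the list alone, among them Fdps, farnesyl diphosphate synthase (5.26 ± 0.08 to 4.39 ± 0.34), and Idi1, the isomerase before it (−0.57). The call held without any single array. Osteoclast genes (19 genes, median −0.10, mean −0.52, 13 negative, adjusted p = 0.0162; adjusted p = 0.710 with an estimated correlation) had 4 lower members adjusted over the list alone, including Atp6v0d2, a proton pump subunit (−0.59 ± 0.08 to −2.26 ± 0.37), and Acp5, tartrate-resistant acid phosphatase (6.41 ± 0.19 to 5.12 ± 0.30). Their median was −0.22 and −0.20 within the slides and −0.10 with a slide term. The osteoclast call was lost without Fra-2 control 2 (−0.32, adjusted p = 0.0850) or Fra-2 knockout 2 (−0.14, adjusted p = 0.0572), and the median was −0.25 without Fra-2 control 1 and −0.17 without Fra-2 knockout 1.

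Chemokines (23 genes, median −0.45, 21 negative, camera adjusted p = 0.00786; adjusted p = 0.885 with an estimated correlation) included Ccl9, which draws myeloid cells (7.21 ± 0.21 to 5.58 ± 0.54), and Ccl7, which draws monocytes (−0.80). Their median was −0.45 with a slide term, −0.56 and −0.53 within the slides, −0.71 without Fra-2 control 1, −0.28 without Fra-2 control 2 (adjusted p = 0.374) and −0.35 without Fra-2 knockout 1 (adjusted p = 0.346). Mitochondrial respiration (36 genes, median −0.15, 34 negative, adjusted p = 0.0162; adjusted p = 0.885 with an estimated correlation) included Ndufa5 (−0.34) and Ndufv1 (−0.26), subunits of complex I. Its median was −0.15 with a slide term, −0.14 and −0.12 within the slides, −0.24 without Fra-2 control 1, and −0.04 without Fra-2 control 2 or Fra-2 knockout 1 (adjusted p = 0.872 and 0.809). No member of either list passed limma adjusted over the list alone.

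Markers of large resident peritoneal macrophages (27 genes, median 0.36, 21 positive, camera adjusted p = 2.28e-05; adjusted p = 0.773 with an estimated correlation) were 0.36 with a slide term, 0.23 within slide 1 and 0.39 within slide 2. Adjusted over the list alone, 2 were higher: Ltbp1, which binds latent TGF-beta (3.40 ± 0.18 to 4.26 ± 0.10), and Hdc, which makes histamine (2.59 ± 0.58 to 4.44 ± 0.20). Neutrophil markers (14 genes, median 0.38, 10 positive, adjusted p = 0.00786; adjusted p = 0.710 with an estimated correlation) had 2 higher members adjusted over the list alone, S100a9, a subunit of calprotectin (−3.27 ± 1.23 to 1.66 ± 2.02), and Lcn2, which binds siderophores (2.38). Their median was 0.38 with a slide term, 0.38 within slide 1 and 0.74 within slide 2. Both calls held without any single array: the resident macrophage median was 0.64 and 0.16 without Fra-2 controls 1 and 2 and 0.61 without Fra-2 knockout 2, and the neutrophil median 0.66 without Fra-2 control 2 and 0.83 and 0.24 without Fra-2 knockouts 1 and 2. Fosl2, the targeted gene, is itself in the AP-1 list, and its probes went in opposite directions. The AP-1 family (18 genes, median 0.22, 12 positive, camera adjusted p = 0.0108, and 0.885 with an estimated correlation) had Fosl2 on its brighter probe as its 1 higher member adjusted over the list alone, and Jun at 0.55. Its median was 0.22 with a slide term, 0.22 and 0.16 within the slides, 0.07 without Fra-2 control 1 (adjusted p = 0.410), 0.37 without Fra-2 control 2 and 0.13 without Fra-2 knockout 2 (adjusted p = 0.129).

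Mesothelial markers (15 genes, median 0.36, 13 positive, camera adjusted p = 0.0250; adjusted p = 0.885 with an estimated correlation) included C3, the central complement component (8.29 ± 0.46 to 8.99 ± 0.29), and Upk1b, a uroplakin (0.55). Their median was 0.36 with a slide term, 0.41 and 0.33 within the slides, 0.24 without Fra-2 control 2 (adjusted p = 0.209) and 0.14 without Fra-2 knockout 1 (adjusted p = 0.250). Most of those genes were dim in the Fra-2 line, and with a common floor the median was 0.09 (adjusted p = 0.245) and with normexp 0.17 (adjusted p = 0.0537). No member passed limma adjusted over the list alone.

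In 2 lists that camera called in both comparisons, the arrays labelled Fra-1 knockout and Fra-2 knockout went in opposite directions from their controls. Cholesterol synthesis had a median of 0.26 in Fra-1 and −0.43 in Fra-2, and mesothelial genes −0.84 and 0.36, the last 0.09 and not called with a common floor (adjusted p = 0.245). With an estimated correlation none of these calls was kept (adjusted p = 0.890, 0.773, 0.890 and 0.885), and without Fra-1 control 1 cholesterol synthesis had 0.12 in Fra-1 (adjusted p = 0.0750). In the test of the difference, Fra-1 effect minus Fra-2 effect, 10 lists were called by camera at a preset correlation, 7 positive and 3 negative. The lines also differed in Cre driver, Mx for Fra-1 and LysM for Fra-2, and in the thioglycollate label. The difference therefore cannot be assigned to Fra-1 against Fra-2 alone. With an estimated correlation 0 of 37 were called (smallest adjusted p = 0.757), and by directional fry 0 (smallest adjusted p = 0.0607), while mixed fry called 12. A single gene, Capn6, was called (−3.41, SE 0.17, adjusted p = 0.0235); it was below background in both groups of the Fra-2 line and 0.00 with a common floor. With a slide term Capn6 had −3.40 (adjusted p = 0.217), and its adjusted p ran from 0.0180 to 1.0 over the alternatives; it lost its call without any Fra-1 array or either Fra-2 control. By unadjusted p under 0.05, 1238 features were positive and 951 negative.

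Cholesterol synthesis differed between the knockout effects (24 genes, median 0.69, 23 positive, camera adjusted p = 7.31e-10; adjusted p = 0.757 with an estimated correlation), with 0.58 with a slide term and 0.72 within slide 1. Adjusted over the list alone, 12 members were higher, including Sqle (1.29) and Fdps (1.27). Fibroblast markers (17 genes, median −1.74, 15 negative, adjusted p = 3.86e-06; adjusted p = 0.757 with an estimated correlation) had 0 members that passed limma adjusted over the list alone, and were −1.73 with a slide term and −1.55 within slide 1. Mfap5, a microfibril protein, had −1.83. Mean levels of the fibroblast list on the Fra-2 line arrays, −3.18 to −2.31, lay far below the 1.25 and 1.70 of the Fra-1 controls. With genes so dim, a fall in Fra-2 knockouts could be missed. Mesothelial markers (15 genes, median −1.06, 13 negative, adjusted p = 3.64e-05; adjusted p = 0.757 with an estimated correlation) had 4 lower members adjusted over the list alone, including Bnc1 (−2.53) and C3 (−1.54); they were −0.85 with a slide term and −0.52 within slide 1. Markers of large resident macrophages (27 genes, median −0.47, 17 negative, adjusted p = 0.00669; adjusted p = 0.757 with an estimated correlation) had 2 lower members adjusted over the list alone, Gata6, the transcription factor of these cells (−2.39), and Ltbp1 (−2.16). Their median was −0.28 with a slide term, −0.37 within slide 1 and 0.02 without Fra-2 control 2, which reversed it (adjusted p = 0.0895). It was −0.71 without Fra-2 control 1 and −0.14 without Fra-1 knockout 1, and the call was lost without Fra-2 knockout 1 (−0.25, adjusted p = 0.0746) or Fra-1 control 2 (−0.36, adjusted p = 0.0884).

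Hypoxia response genes (22 genes, median 0.86, 18 positive, camera adjusted p = 3.77e-04; adjusted p = 0.757 with an estimated correlation) were 0.66 with a slide term and 1.14 within slide 1, with Car9 at 0.94, and 0.43 without Fra-2 knockout 1. Interferon-stimulated genes (37 genes, median 0.39, 33 positive, adjusted p = 0.00669; adjusted p = 0.757 with an estimated correlation) were 0.38 and 0.77, with Xaf1 and Dhx58, a cell death factor and an RNA sensor, both at 0.68; they had 0.22 without Fra-1 knockout 1 (adjusted p = 0.307), 0.42 without Fra-1 control 2 (adjusted p = 0.0985) and 0.59 without Fra-1 knockout 2. Osteoclast genes (19 genes, median 0.49, 14 positive, adjusted p = 0.0112; adjusted p = 0.757 with an estimated correlation) were 0.49 and 0.37 in the same order and had 2 higher members adjusted over the list alone, with Dcstamp, which fuses osteoclasts, at 1.92 and Atp6v0d2 at 1.64; without Fra-2 knockout 2 the median was 0.32. The unfolded protein response (24 genes, median 0.28, 20 positive, adjusted p = 0.0227; adjusted p = 0.757 with an estimated correlation) was 0.21 both ways, with Psat1 of serine synthesis at 1.14 and Calr at 0.58, and lost its call without Fra-1 control 1 (0.24, adjusted p = 0.102) or Fra-2 knockout 2 (0.28, adjusted p = 0.0781), with 0.18 without Fra-1 knockout 2. 

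Glycolysis (22 genes, median 0.40, 18 positive, camera adjusted p = 0.0112; adjusted p = 0.850 with an estimated correlation) and mitochondrial respiration (36 genes, median 0.18, 34 positive, adjusted p = 0.0112; adjusted p = 0.850 with an estimated correlation) were 0.50 and 0.18 within slide 1. With a slide term both calls were lost (0.31, adjusted p = 0.0767, and 0.11, adjusted p = 0.115), and both were lost without Fra-2 control 2 (0.30 and 0.12) or Fra-2 knockout 1 (0.17 and 0.09). The glycolysis call was also lost without Fra-1 control 1 (0.39) or Fra-1 knockout 1 (0.44), and the mitochondrial call without Fra-1 control 2 (0.13) or Fra-1 knockout 2 (0.14); without Fra-2 knockout 2 they were 0.71 and 0.28. No member of the hypoxia, interferon, unfolded protein, glycolysis or mitochondrial lists passed limma adjusted over the list alone. Arg1 differed by 4.85 between the knockout effects (adjusted p = 0.416).

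By unadjusted p under 0.05, 313 features passed in both knockout comparisons: 48 higher in both (23.5 expected), 104 lower in both (72.3), 76 higher in Fra-1 and lower in Fra-2 (45.3), and 85 the reverse (37.5). In 50 simulations of unchanged groups that shared the estimate of spread, the ratios to expectation were 3.11, 3.13, 3.16 and 3.05, above those observed. The simulated noise was independent between features and none changed. In the data 2025 and 2020 features passed, against 1146 expected by chance. The ratios are therefore not directly comparable and cannot show less sharing than chance. The Pearson correlation of log2 fold changes across features was 0.031 and the Spearman correlation −0.035, where genes are not independent replicates, and no control array was shared between the comparisons.

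Between the floxed controls of the lines, markers of large resident macrophages, mast cells and B cells, NF-kappaB targets and inflammatory cytokines were lower in the Fra-1 line, and fibroblast, mesothelial, cell cycle and lysosome genes higher, by camera at a preset correlation. With an estimated correlation 0 of 37 lists were called (smallest adjusted p = 0.458), by directional fry 26 and by mixed fry 36. Only the Fra-1 line was labelled thioglycollate elicited, so line, elicitation label and preparation went together, and both Fra-1 controls were on slide 1. A total of 8252 features were called, 4149 higher and 4103 lower in Fra-1 controls (2448 and 2514 by at least 2-fold), and 71.8% had arrays that did not overlap, where chance gives 33.3%. With a slide term 7427 were called.

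The 12 largest falls and 12 largest rises among genes whose arrays did not overlap between the controls follow. Timd4, the phosphatidylserine receptor Tim-4 of resident macrophages, fell from 4.72 ± 0.24 to −6.74 ± 0.06, at least 822-fold (adjusted p = 6.73e-05). Il1b, the inflammatory cytokine, fell by 9.80, Alox15, a lipoxygenase of resident cells, by 8.05, the formyl peptide receptors Fpr1 and Fpr2 by 8.02 and 8.01, and Apoc1, an apolipoprotein, by 7.75. Cd163, the haemoglobin scavenger receptor, fell at least 55.6-fold, and Nt5e, the ectonucleotidase CD73, fell by 7.74. Serpinb10, a serine protease inhibitor (at least 82.1-fold), Ly6f, a Ly6 surface protein (157-fold), Meox1, a homeobox factor (50.3-fold), and Fam167b, of unknown function (177-fold), also fell. Bex1, an adaptor first described in neurons, rose from −6.86 ± 0.03 to 5.49 ± 0.38, at least 1086-fold (adjusted p = 7.43e-05). Npy, neuropeptide Y, rose by 9.22, Mamdc2, a matrix proteoglycan, by 8.84, Dio2, a thyroid hormone deiodinase, by 7.96, Mgll, monoglyceride lipase, by 7.83, and Ctsk, cathepsin K, by 7.63. Prss46, a serine protease (266-fold), Htr2b, a serotonin receptor (205-fold), Cavin2, of caveolae (116-fold), Pdgfra, the PDGF receptor of fibroblasts (103-fold), Slco2b1, an anion transporter (63.1-fold), and Tceal7, a transcription elongation factor-like gene (47.9-fold), rose by at least those folds.

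Among genes named in every comparison, Fosl2 fell from 5.54 ± 0.04 in Fra-2 controls to 2.99 ± 0.19 in Fra-1 controls (−2.55, adjusted p = 9.09e-04) and Nos2 from −0.35 ± 0.26 to −2.68 ± 0.41 (adjusted p = 0.00731). Arg1 (−2.62, adjusted p = 0.105), Lyz2 (−0.70, adjusted p = 0.0582) and Casp4 (−1.52, adjusted p = 0.0840) were not called.

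Camera called 18 of 37 lists between the controls, 5 higher and 13 lower in the Fra-1 line, all lost with an estimated correlation (every adjusted p at least 0.458). A filter on all 8 arrays ended the calls of mesothelial markers (1.21, adjusted p = 0.350), inflammatory cytokines (−0.96, 0.0901), chemokines (−0.67, 0.371) and T and NK cell markers (−0.82, 0.321). A common floor ended those of chemokines (−1.04, 0.0742) and T and NK markers (−0.63, 0.120), no filter that of chemokines (−1.01, 0.0673), and quantile normalization that of the unfolded protein response (0.32, 0.0622). Normexp ended those of the unfolded protein response (0.32, 0.0584) and T and NK markers (−0.48, 0.0584), a trended prior that of T and NK markers (−1.02, 0.0593), and the mean of probes that of chemokines (−1.14, 0.05). Cell cycle genes had a median of 1.64 (30 higher and 0 lower of 39; camera adjusted p = 9.30e-12), with Stmn1, which destabilizes microtubules (3.85), and Tpx2, of the spindle (3.78). Fibroblast markers had 5.00 (15 and 1 of 17; 3.05e-07), with the collagen chains Col1a2 (6.29) and Col1a1 (6.27). Lysosome genes had 1.13 (18 and 2 of 28; 9.00e-06), with Lipa, acid lipase (2.63), Acp5 (2.03) and Cd68 (1.93) higher and Ctsc, cathepsin C, lower (−2.21). Mesothelial markers had 2.26 (11 and 2 of 15; 0.00225), with Wt1, a mesothelial transcription factor (5.43), and Lrrn4 (at least 20.9-fold). The unfolded protein response had 0.35 (9 and 3 of 24; 0.0351), with Psat1 and Trib3, a stress pseudokinase (1.64); its call was lost without Fra-2 control 1 (0.33, adjusted p = 0.0582) or Fra-1 control 2 (0.28, adjusted p = 0.0829). With a slide term these lists had 1.71, 4.77, 1.16, 1.86 and 0.38, and within slide 1 1.79, 5.32, 1.12, 1.88 and 0.37. Of their members, adjusted over the list alone, 34, 15, 19, 12 and 10 were higher.

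Markers of large resident macrophages had a median of −3.65 in Fra-1 controls (2 higher and 21 lower of 27; camera adjusted p = 2.12e-08), with Selp, P-selectin, at −7.39. NF-kappaB targets had −2.31 (1 and 18 of 22; 2.12e-08), with Marco, a scavenger receptor (−6.76), Ier3, an early response gene (−4.26), and Saa3, serum amyloid A3 (−3.91). Inflammatory cytokines had −1.54 (1 and 9 of 18; 0.00554), with Il6 at −5.79, and complement and coagulation −1.77 (6 and 14 of 23; 0.00225), with Cfb, factor B (−7.20), and C4b (−5.39). Pattern receptors had −0.94 (4 and 16 of 30; 4.77e-04), with Clec4n, the lectin Dectin-2 (−5.87), and Tlr2 (−4.22). Interferon-stimulated genes had −0.74 (2 and 23 of 37; 8.96e-05), with Gbp5, a guanylate-binding protein (−5.44). MHC class II presentation had −1.07 (0 and 10 of 15; 6.75e-05), with H2-DMb2 (−4.03) and the costimulator Cd86 (−3.96). With a slide term these lists had −3.85, −2.19, −1.05, −1.83, −0.85, −0.70 and −1.09, and within slide 1 −3.93, −2.21, −1.10, −1.84, −0.86, −0.67 and −1.07. Members lower adjusted over the list alone numbered 21, 19, 9, 14, 17, 23 and 10.

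Mast cell and basophil markers had a median of −4.78 (0 higher and 11 lower of 11; camera adjusted p = 2.20e-06), with Mcpt4, a mast cell protease (−7.01), and B cell markers −3.96 (1 and 16 of 19; 8.96e-05), with Cd79a, a signalling chain of the B cell receptor (at least 13.9-fold), and Ms4a1, CD20 (−4.92). General macrophage markers had −0.67 (2 and 9 of 18; 0.00304), with Cd14, the endotoxin co-receptor (−3.94). Cholesterol synthesis had −0.68 (3 and 13 of 24; 0.0107), with Tm7sf2, a sterol reductase (−1.06), lower but Srebf2, its regulator, higher on its brighter probe (2.26) and lower on the other (−0.86, adjusted p = 0.00627). Chemokines had −1.14 (5 and 12 of 23; 0.0439), with Ccl24 (−7.30), an eosinophil attractant, lower and Ccl8, a monocyte attractant, higher (6.07). T and NK cell markers had −1.02 (4 and 10 of 19; 0.0439), with Cd3d, of the T cell receptor (−3.45), lower and Il7r, the interleukin 7 receptor, higher (5.54). With a slide term these lists had −4.95, −4.48, −0.58, −0.59, −0.93 (call lost, adjusted p = 0.0718) and −1.08, and within slide 1 −5.19, −4.14, −0.53, −0.58, −1.27 and −0.70. Adjusted over the list alone, 11, 16, 11, 14, 12 and 10 of their members were lower. The chemokine call was lost without Fra-2 control 2 (−1.27, adjusted p = 0.132) or Fra-1 control 1 (−0.73, adjusted p = 0.145), and the T and NK call without either Fra-2 knockout array (adjusted p = 0.0671) or Fra-1 control 1 (−0.99, adjusted p = 0.0897).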

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

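The tests of Plb1 against the array floor, of the stromal members and of slides for them, and of Fra-1 control 1 were chosen only after the results had been seen, whereas the test of a wide stretch around Fosl2, the tests of the difference and the leaving out of arrays had been set before.

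Plb1, a phospholipase gene 1 place from Fosl2 among tested named genes, was chosen after its values were seen. It was −6.71 and −6.67, below background, on Fra-2 control arrays and −2.90 and −2.63 in knockouts (fitted difference 3.93, SE 0.43, adjusted p = 0.0962, not called; 3.81 and 4.04 within the slides; 1.09 with a common floor; adjusted p 0.0448 to 0.260 over the alternatives), and below background in the Fra-1 line. Fra-2 knockout 1, the dimmest array, could have set such a gap, but both knockout arrays were above background and the lower lay 0.95 above the highest detection level of any array, which argues against the dim array as the whole cause. A wide stretch of 129 chromosome around Fosl2 might also alter neighbours. Over 20 named neighbours, Plb1 left out, the median absolute log2 fold change was 0.132. Features not matched to a gene name were not part of this test. The 95th percentile over 14015 runs of genes was 0.278. That argues against a broad change across these neighbours, but a median cannot show a change in a few of them. By the labels, both Fra-2 groups had the same floxed genotype at Fosl2. Transcription running on from the recombined Fosl2 allele is possible and was not tested, since probe positions in the deleted part were unknown.

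Fibroblast (−1.29) and mesothelial (−0.84) genes were lower in Fra-1 knockouts by camera at a preset correlation, with adjusted p = 0.890 for both with an estimated correlation, and the mesothelial call was lost without Fra-1 control 2 (−0.50, adjusted p = 0.0589). A difference between slides could add to this. With a slide term the medians were −1.47 and −0.45, both still called by that test, although the mesothelial median shrank from −0.84. That term cannot decide this. Both Fra-1 controls were on slide 1, so it drew mostly on the Fra-2 line, where these genes were dimmer. Within slide 1 the medians stayed negative, −1.02 and −0.71, though on a single Fra-1 knockout array. Fewer of these cells in the culture could lower both lists and stays open: 88.9% of 27 members above background on all 4 arrays of the line were negative, but this restates the lists that prompted the test and decides nothing. Regulation by Fra-1 inside those cells also stays open and was not tested.

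The hypoxia list (0.48), the glycolysis list (0.25) and Arg1 (2.31) in the Fra-1 comparison may rest on Fra-1 control 1. Without it they had 0.28, 0.21 and 0.59, and without Fra-1 control 2 0.73, 0.32 and 4.03. That fits Arg1, but its values on single arrays had been seen and fixed this outcome, so the test adds no support. Hypoxia is left undecided. Arg1 is itself in the hypoxia list, and Slc2a1 and Pdk1 are in both lists, so these items are not independent. The glycolysis median kept most of its value without Fra-1 control 1, but its camera call was lost, so that list is undecided too.

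The results below passed limma or camera at a preset correlation in the test of the difference, Fra-1 effect minus Fra-2 effect; with an estimated correlation 0 of 37 lists were called (smallest adjusted p = 0.757) and by directional fry 0 (smallest adjusted p = 0.0607), while mixed fry called 12. The lines also differed in Cre driver and thioglycollate label, so these differences cannot be assigned to Fra-1 against Fra-2 alone. Capn6 had −3.41, and 0.00 with a common floor. Cholesterol synthesis had a median of 0.69. Fibroblast markers, which were dim in the Fra-2 line, had −1.74. Mesothelial markers had −1.06. Hypoxia response genes had 0.86. Osteoclast genes had 0.49. Large resident macrophage markers had −0.47, and 0.02 without Fra-2 control 2. Glycolysis had 0.40. Interferon-stimulated genes had 0.39. The unfolded protein response had 0.28. Mitochondrial respiration had 0.18. Leaving out single arrays ended the calls of the glycolysis, interferon, mitochondrial, unfolded protein and resident macrophage lists, and of Capn6.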

How the results depend on the processing

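Normexp on median signals, used because the files hold no mean raw signal, and the common floor were chosen only after the data had been seen; the other alternatives were set beforehand. Counts of called features were 3 in Fra-1, 2 in Fra-2, 1 for the difference and 8252 between controls. With quantile normalization the knockout counts and the difference gave 21, 18 and 10, the last without Capn6. With normexp they were 0 (2259 by unadjusted p), 19 and 1, the last another gene. Without a filter all were 0 (2298, 2649 and 2341 by unadjusted p), and with a slide term 0 (2011, 2333 and 2123). A filter on all 8 arrays gave 0 (1448 by unadjusted p), 4 and 0 (1653). A trended prior gave 0 (2127), 57 and 0 (2311). With only the groups compared, Fra-1 had 1, another feature, and Fra-2 0 (1416), and with pooled controls Fra-1 had 6 and Fra-2 0 (1539). The common floor gave Fra-1 11, which did not include any of the 3 called in the main fit. Between controls, a log2 fold change of at least 1 gave 4962, and the other alternatives with all arrays 6291 (no filter) to 8940 (trended prior), within 1.5 times of 8252. Leave-one-out counts ran from 0 to 18 in Fra-1 (0 without either Fra-2 control, 18 without either Fra-2 knockout), 0 to 46 in Fra-2 (0 without either Fra-1 knockout, 46 without Fra-2 knockout 2), 0 to 27 for the difference (27 without Fra-2 knockout 2) and 5592 to 8541 between controls, where a lone array was assumed to vary like the other groups. For lists, 10, 8, 10 and 18 were called by camera; with an estimated correlation 0 were, in each comparison, with directional fry 0, 0, 0 and 26, and with mixed fry 2, 13, 12 and 36. Pooled controls gave 6 lists in Fra-1. Lists called ran from 5 to 11, 7 to 13, 8 to 14 and 17 to 20 in leave-one-out. Features called in both knockouts were 0, where under 1 is expected from 3 and 2 calls, and 313 by unadjusted p. Pooled controls reversed, in Fra-1, cell cycle (0.72), cholesterol synthesis (−0.049), fibroblast (1.18), interferon (−0.21), mesothelial (0.43) and MHC class II (−0.28) medians, and in Fra-2 chemokines (0.24) and mesothelial markers (−0.67); pooling adds the difference between the lines to the comparison by construction. In leave-one-out, cell cycle in Fra-1 ran from −0.36 to 0.071, reversed without Fra-1 control 2, and large resident macrophage markers in the difference from −0.71 to 0.021, reversed without Fra-2 control 2. For the other changes the cause was not tested. Across alternatives, lists of Fra-1, Fra-2, the difference and the controls were counted as the same 164, 145, 160 and 333 times and lost their call 47, 32, 36 and 38 times. Named genes were counted as the same 1639, 1670, 1201 and 2695 times. For a gene called in neither fit, that count takes no account of direction. Few named genes were called in the knockout comparisons, so it says little about stability there. Within slides the counts compare size, with no threshold. No paired analysis was possible because the labels link no knockout mouse to a control mouse; slides, which in the Fra-2 line hold 1 array of each group, entered as the slide term. Signal over background limits the features called in Fra-1: all were below background in knockouts, and a common floor left each of them at 0.00.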

Other observations

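The genes named in this paragraph were called only when adjusted over their list alone, in lists that camera did not call, in the Fra-2 comparison. Among genes of the liver X receptor and lipid efflux (20 genes, 8 positive and 12 negative, median −0.11), 4 were lower, including the receptor gene Nr1h3 itself (3.36 ± 0.28 to 1.46 ± 0.37, −1.90; −1.97 and −1.84 within the slides) and Lpl, lipoprotein lipase (−0.84). Lysosome genes had 3 lower members, including Cd63, a tetraspanin of late endosomes (7.60 ± 0.18 to 6.24 ± 0.12; −1.57 and −1.15 within the slides). Alternative activation genes split, with 3 higher, among them Chil3, the lectin Ym1 (−0.07 ± 0.33 to 3.04 ± 0.75; 3.87 and 2.35 within the slides), and 1 lower, Mrc1, the mannose receptor (−0.69). Monocyte and small macrophage markers had 3 higher, including Ifitm6 (1.45), and 4 lower. Among pattern receptors, Nod1, a sensor of peptidoglycan, had 0.77 and Cd36, a receptor for oxidized lipid, −1.21. In MHC class II presentation, Cd86 had 0.87 and H2-Ab1 −0.62.

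Between the controls, some lists that camera did not call held called members in both directions. Osteoclast genes had 7 higher and 6 lower of 19 in Fra-1 controls, with Atp6v0d2 (7.38) and Itgb3, the vitronectin receptor beta chain (3.68 on its brighter probe, −2.13 on the other), higher. Eicosanoid metabolism had 3 higher and 8 lower of 19, with Hpgds, a prostaglandin D synthase (4.76), higher and Alox5, which starts leukotrienes (−5.64), and Ptgs2, cyclooxygenase 2 (−3.39), lower. Alternative activation had 7 higher and 12 lower of 22, with Chil3 (6.56) and Pparg, a lipid-sensing receptor (5.36), higher. Uptake of apoptotic cells had 10 higher and 11 lower of 26, with Stab2 (at least 23.4-fold) and the bridging protein Mfge8 (4.13) higher. The AP-1 family had 5 higher and 5 lower of 18, with Atf3 (3.16), Jun (2.61) and Batf3 (1.65) higher. Arginine metabolism had 8 higher and 3 lower of 16, with Arg2 (−6.29) and Ass1, which remakes arginine (−3.63), lower. Mitochondrial respiration had 0 of 36 called by limma, and 3 higher and 1 lower by unadjusted p under 0.05.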
